A study of Mus musculus with 4 samples.

How the data were processed

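Gene expression was measured on 4 Agilent 1-colour mouse arrays, each hybridised with Cy3-labelled RNA from the dorsal hippocampus of female mice, taken after a set of behavioural tests. Per the labels, 2 arrays carried control samples (replicates 2 and 3) and 2 carried samples from mice on a 20-fold iodine intake (replicates 2 and 3). Other replicates, such as any numbered 1, were not analysed here. The labels do not say that the replicates were separate animals, so every p-value measures only the spread between these samples, which may be technical. All 4 arrays lay on 1 slide and were read in 1 scan. The controls occupied slide columns 1 and 2 and the iodine samples columns 3 and 4, so position on the slide and group cannot be told apart, and a fit with slide as a block was not possible.

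The authors deposited the scanner output of each array, made with Agilent Feature Extraction 12.1.1.1 per the file headers. The deposited intensity used here is the processed signal, which per the file headers was background-subtracted and corrected for spatial trends within the array, and was not normalized between arrays. The median spot and background intensity columns, also deposited, were used for 1 alternative. Flags for signal well above background, saturation and outlier spots were taken as the authors deposited them. Each array held 62976 spots, of which 3671 were controls. The other 59305 spots gave 56605 probes after spots of a probe were averaged, leaving out spots flagged as outliers (47 to 70 per array). No spot was saturated.

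Processed signals were put on the log2 scale, and each array's 75th percentile over non-control probes was subtracted (the mean of the percentiles was added back). The 75th percentile of the processed signal was 158.8 and 154.2 in the control arrays and 149.7 and 144.3 in the iodine arrays. Probes well above background on at least 2 of the 4 arrays, whatever the group, were kept, which left 38231 probes. Genes were named by matching the probe's transcript accession, without its version, to a RefSeq gene table of assembly GRCm38.p6. This named 32994 probes (58.3%) of 22911 genes, and the remaining 23611 probes were counted without a gene name. The array's own header names an older build, so no coordinates are given. Each gene was represented by its brightest kept probe. Of the 16793 genes tested, 6092 had several kept probes, and in 2905 of those the probes differed in sign.

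A gene with no probe well above background on either array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against the dimmer group's mean of the higher of 2 values per array, the lowest signal among probes well above background and the probe's own signal. Where 1 of a group's 2 arrays measured a gene, the fitted difference is given with that number.

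The comparison was 20-fold iodine minus control, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Files were read with the R package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15. A descriptive limit was also counted, with an unadjusted p under 0.05, a fold of at least 1.5 and no overlap between the groups' arrays. Gene lists were tested with camera (two-sided, preset inter-gene correlation of 0.01), adjusted over the 43 of 44 lists with at least 3 genes tested. The Y-linked list had 0 genes tested. The lists were written from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for named genes. Members were also adjusted over their list alone, a step that the design did not hold and that was not adjusted for the number of lists. In 4 lists at least 1 member passed it. List members under older symbols were matched through the synonyms of the gene table, so Cyr61 appears as Ccn1 and Ctgf as Ccn2.

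The rule named 10 genes higher and 10 lower by unadjusted p among those with a fold of at least 1.5 and no overlap, leaving out predicted gene models, since no gene passed the adjusted threshold. It also named the 2 members of each list with the smallest unadjusted p, or 4 in the thyroid hormone lists and in lists past the threshold, and 18 genes fixed in advance. In all 137 genes were named in this way, and 14 of them had another kept probe of opposite sign, among them Kcnq1, Cd247, Map3k10, Rxra, Grik2, Shank3, Gabra3, Nrg3, Dnajb9, Nwd2, Mbp and Dcx. Some genes that the rule names are not reported here. Values of genes are log2 differences with the standard error (SE) of the fit or a 95% confidence interval, on 2 arrays per group.

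The alternatives were normexp background correction (offset 50), quantile normalization, both together, scaling to the median of probes detected on all arrays, no filter and a stricter filter on dim probes, an intensity trend with robust variances, the mean of a gene's probes, every probe on its own, the replicate number as a block, leaving out each array, an adjusted threshold of 0.1, camera with an estimated correlation, camera on ranks, and fry. Where an array was left out, the lone array of its group was assumed to vary like the other group, so all spread came from 1 pair. Normexp was planned on the mean spot signal, which was not used here, and was run on the median spot signal in its place. The fit was tested on simulated data with the 16793 genes and 2 samples per group. It recovered 58.2% of 67 genes changed 2-fold, 88.1% of 67 changed 4-fold and 98.5% of 66 changed 16-fold, with 6 false calls. All 200 genes were changed in the same simulation, and their spread was drawn from the model that the fit assumes. With fewer changed genes the adjusted threshold is harder to reach, so these shares do not give the power for few changes. Without any change the fit called 0 genes and 0 lists. The simulated genes varied independently, so this cannot show how the list test behaves where the members of a list vary together. A simulated list shifted by 0.7 on 1 array alone had an adjusted p of 2.5e-07 with the preset correlation and 0.973 with an estimated one. The number of arrays limits the precision: the median 95% interval of a gene reached 0.26 log2 units to either side, 1.20-fold.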

Results

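The arrays profiled messenger RNA in the dorsal hippocampus of female mice kept on control or 20-fold iodine intake, with 2 arrays per group, to ask whether excess iodine altered expression in the brain. Iodine is the substrate of thyroid hormone synthesis. The arrays were alike in depth. Between 37533 and 37921 of 56605 probes were well above background on each, and the median coefficient of variation of repeated spots was 2.27 to 3.23%. Pearson's r between arrays over 16793 genes was 0.994 to 0.996 (genes are not independent replicates). It was 0.9955 between the 2 controls, 0.9946 between the 2 iodine arrays and 0.9942 to 0.9957 across the groups, so likeness did not follow the groups. Xist, the transcript of the inactive X chromosome, had log2 signals of 6.77 to 7.14 on all 4 arrays (difference -0.14), and 0 of 9 probes of the Y-linked list were well above background, as the female label requires.

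At the level of gene groups, interferon response, antigen presentation, glucocorticoid response, circadian clock and cholesterol synthesis genes were lower in the 20-fold iodine group, and pituitary and hypothalamic hormone genes were higher. These 6 of 43 lists passed by camera with the preset correlation. With an estimated correlation 0 lists passed (adjusted p = 0.80 for each of the 6), as by fry (smallest adjusted p = 0.094). The other 2 ways to split the 4 arrays into pairs gave more lists by the same test, 11 and 14. Without control replicate 3 the interferon, antigen presentation and cholesterol medians shrank to -0.07, -0.22 and -0.05. Genes regulated by thyroid hormone in brain did not pass as a group. No single gene passed limma's adjusted p of 0.05 among 16793 (smallest adjusted p = 0.668), against 1239 genes with an unadjusted p under 0.05, 653 higher and 586 lower, where chance gives 839.65. The arrays of the groups did not overlap in 6693 genes (39.9%, where chance gives 33.3%). The descriptive limit held 174 genes, 85 higher and 89 lower, of which 28 were predicted models and 47 were not well above background in 1 of the groups. That count was 388 without control replicate 2 (173 higher, 215 lower), 325 without control replicate 3 (179 higher, 146 lower), 336 without 20-fold iodine replicate 2 (228 higher, 108 lower) and 437 without 20-fold iodine replicate 3 (78 higher, 359 lower), so the balance of directions depends on single arrays. Leaving out an array leaves 1 in its group, which is assumed to vary like the other group, so these counts and the p-values below without an array rest on the spread of 1 pair. Among the 13628 probes without a gene name, 0 passed and 1557 had an unadjusted p under 0.05.

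**Figure D1:**
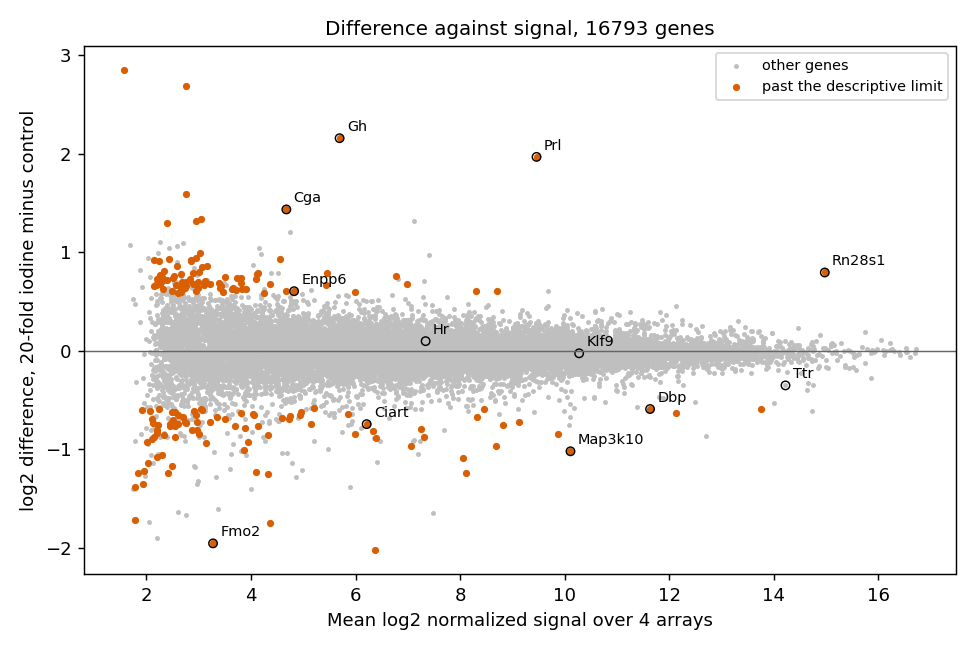
Log2 difference (20-fold iodine minus control) against mean log2 normalized signal for each of 16793 genes, with the 174 genes past the descriptive limit in orange. Gh (2.16), Prl (1.97) and Cga (1.43) lie far above 0, Map3k10 (-1.02) below it, and Hr (0.10) and Klf9 (-0.03) near it, and no gene passed the adjusted threshold. Genes not well above background in a group, such as Fmo2, are drawn at their measured means, where the difference is only bounded.

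The genes with the smallest unadjusted p among those higher in iodine were a mixed set, none past the threshold (adjusted p = 0.668 for all 20 genes here). Rn28s1, a ribosomal RNA and the brightest of them, had a log2 difference of 0.79 ± 0.08 (SE, n = 2 per group), and Capn11, a calpain protease, 0.76 ± 0.07. Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes, stood at 0.60 ± 0.07, Cuedc1 at 0.67 ± 0.08 and Pabpc5 at 0.63 ± 0.08. The potassium channel gene Kcnq1 had 0.75 ± 0.07 and the T cell receptor zeta chain gene Cd247 0.60 ± 0.08, but other probes of both genes gave differences down to -0.26 and -0.57. The olfactory receptor gene Olfr122 had 0.92 ± 0.08. Cyp2g1, an olfactory cytochrome P450, and Olfr806 were not well above background in controls and were at least 1.81-fold and 1.54-fold brighter in iodine.

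On the lower side, the kinase gene Map3k10 had a log2 difference of -1.02 ± 0.11, with another probe at 0.33. Dus4l, a dihydrouridine synthase, had -0.88 ± 0.10, Efcab2 -0.84 ± 0.08 and Xdh, which makes uric acid, -0.75 ± 0.08. Fmo2, a flavin monooxygenase, was not well above background in the iodine group and was at least 3.71-fold brighter in controls. The same held for the telomere protein gene Pot1b (at least 1.44-fold), Irs4 (1.28-fold), Ms4a4b (1.18-fold), Olfr559 (1.17-fold) and the leukotriene receptor gene Cysltr1 (1.16-fold). Olfr559 and Cysltr1 changed sign with normexp, to 0.01 and 0.02. Over all settings the fitted difference of Fmo2 ranged from -2.15 to -0.25, that of Ms4a4b from -1.46 to -0.01 and that of Irs4 from -1.21 to -0.02. The settings include normexp, whose offset of 50 draws the differences of dim genes toward 0.

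Interferon-induced genes were lower in iodine in 26 of 26 members, with a median log2 difference of -0.30 (camera adjusted p = 3.4e-06, and adjusted p = 0.80 with an estimated correlation). Ifit3 had -0.79 ± 0.12 (SE), Ifit1 -0.92 ± 0.20, Ifih1, a sensor of viral RNA, -0.56 ± 0.16 and Ifit2 -0.56 ± 0.20, and 0 members passed adjusted over the list alone or over all genes. Antigen presentation genes were lower in 15 of 15 members, with a median of -0.69 (adjusted p = 1.4e-04, and adjusted p = 0.80 with an estimated correlation) and 0 members past either threshold. B2m, the light chain of class I molecules, had -0.52 ± 0.24 and the class II gene H2-Eb1 -0.91 ± 0.42. Ciita, the class II activator, had -1.18 ± 0.46 and H2-Aa -1.36 ± 0.57, both well above background on 1 of 2 iodine arrays. The members' median deviations from their 4-array means in control replicates 2 and 3 and iodine replicates 2 and 3 were -0.11, 0.48, -0.33 and -0.12 for the interferon list, and -0.09, 0.76, -0.45 and -0.17 for antigen presentation. On the same arrays meninges and fibroblast genes stood at -0.03, 0.23, -0.71 and 0.34 and microglia genes at -0.09, 0.13, 0.04 and -0.08. Without control replicate 3 neither list passed, with medians of -0.07 (adjusted p = 0.207) and -0.22 (adjusted p = 0.094). Without control replicate 2 the medians were -0.70 and -1.18, without 20-fold iodine replicate 3 the interferon median was -0.49, and with normexp they were -0.19 and -0.42.

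**Figure D2:**
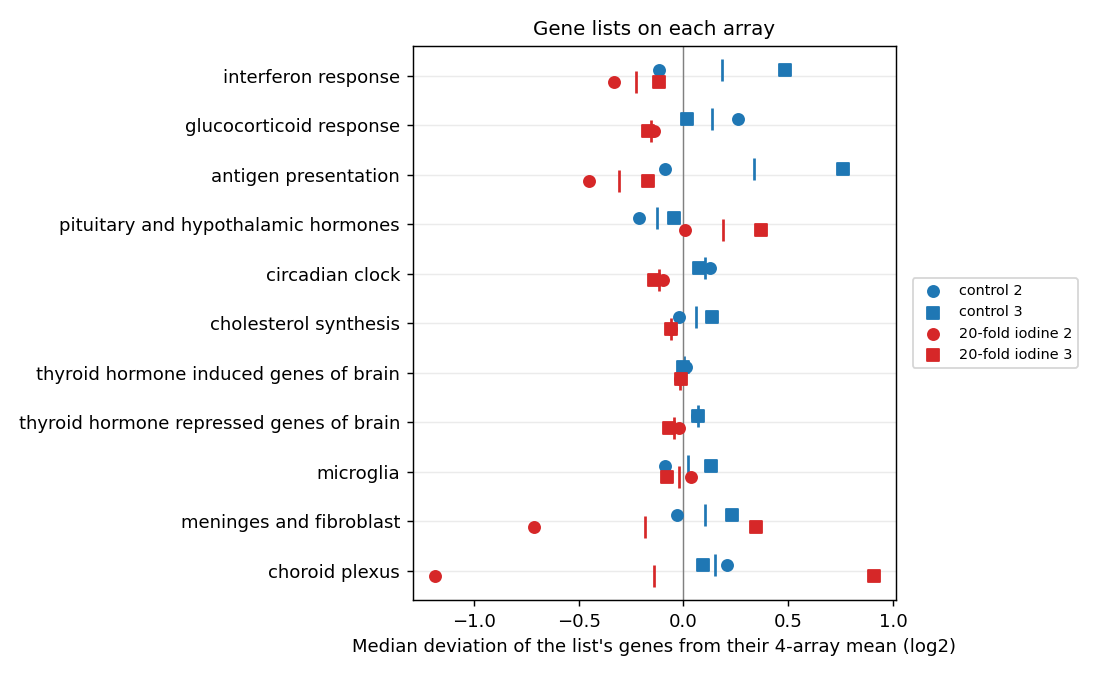
Median deviation of each list's genes from their 4-array mean (log2) on each array, with controls in blue, 20-fold iodine in red, circles for replicate 2, squares for replicate 3 and bars for the mean of each group's pair. Control replicate 3 stands apart for the interferon (0.48) and antigen presentation (0.76) lists, the clock and glucocorticoid lists separate the groups, and the 2 iodine arrays lie far apart for choroid plexus genes (-1.19 and 0.91).

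Glucocorticoid-responsive genes were lower in iodine in 19 of 20 members, with a median log2 difference of -0.34 (adjusted p = 1.3e-05, and adjusted p = 0.80 with an estimated correlation). Per1 had -0.48 ± 0.09 (SE), Errfi1, an inhibitor of EGF receptor signalling, -0.34 ± 0.09, Ddit4, an inhibitor of mTOR, -0.28 ± 0.08 and the metallothionein gene Mt1 -0.40 ± 0.12. Another kept probe of Mt1 gave -0.01. None of the 20 passed adjusted over the list alone or over all genes, and the median was -0.21 without control replicate 2. Rn28s1, a ribosomal RNA, separated the groups as this list and the clock list did. Its normalized log2 signals were 14.61 and 14.55 in controls and 15.41 and 15.34 in iodine. The rule that named Rn28s1 required such a separation, which 39.9% of all genes had, and a link to these lists was not tested.

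Circadian clock genes were lower in 13 of 17 members, with a median of -0.18 (adjusted p = 0.0056, and adjusted p = 0.80 with an estimated correlation). Adjusted over the list alone 6 of the 17 passed, against 0 over all genes. Of these, 5 were lower: Ciart, a repressor of the clock, at -0.75 ± 0.13 (SE), Dbp, a clock output factor, at -0.59 ± 0.12, Per2 at -0.50 ± 0.13, Per3 at -0.50 ± 0.07 and Per1, which is also in the glucocorticoid list, at -0.48 ± 0.09. The sixth, Nr1d1, which encodes the repressor REV-ERB alpha, was higher at 0.47 ± 0.09. Per3 had another kept probe at -0.17 and Ciart another at -0.61. Dbp and Per2 are not among the genes of the naming rule and were added after their values were seen. The list's median was -0.27 without control replicate 2.

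**Figure D3:**
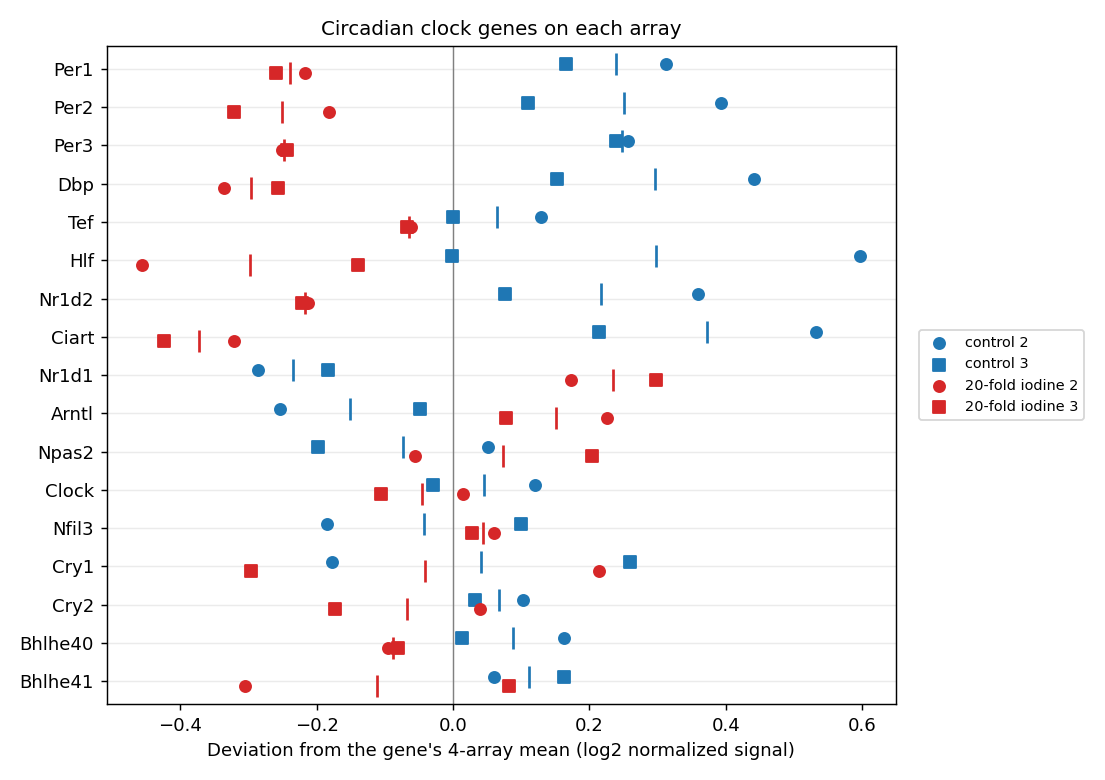
Deviation of each of 17 clock genes from its 4-array mean (log2 normalized signal) on each array, with controls in blue, 20-fold iodine in red, circles for replicate 2, squares for replicate 3 and bars for the mean of each group's pair. Per1, Per2, Per3, Dbp and Ciart lie lower on both iodine arrays than on both control arrays, and Nr1d1 lies higher.

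Hormone genes of the pituitary and hypothalamus were higher in 10 of 13 members, with a median log2 difference of 0.24 (adjusted p = 0.0056, and adjusted p = 0.80 with an estimated correlation). Growth hormone (Gh) had 2.16 ± 0.31 (SE) and Cga, the alpha subunit shared by thyrotropin and the gonadotropins, 1.43 ± 0.19, and these 2 of 13 passed adjusted over the list alone, against 0 over all genes. Prolactin (Prl) had 1.97 ± 0.69, with log2 signals of 7.54 and 9.42 in controls and 10.73 and 10.16 in iodine, and Pomc 0.24 ± 0.10. Tshb and Fshb were not well above background on enough arrays to be tested. The list's median deviations in control replicates 2 and 3 and iodine replicates 2 and 3 were -0.21, -0.04, 0.01 and 0.37. Choroid plexus (0.91) and thalamus and habenula genes (0.36) also stood highest on iodine replicate 3. Gh and Prl, in contrast, were brighter on iodine replicate 2 than on iodine replicate 3 (6.89 and 6.66 for Gh). The list's median was 0.41 without 20-fold iodine replicate 2, and 0.16 and 0.10 in the alternatives with normexp. Over all settings Gh ranged from 1.01 to 2.58, Cga from 0.50 to 1.69 and Prl from 1.03 to 2.91.

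Cholesterol synthesis genes were lower in 18 of 22 members, by a median of -0.11 (adjusted p = 0.019, and adjusted p = 0.80 with an estimated correlation), with 0 members past either threshold. Lss had -0.20 ± 0.07 (SE), Stard4, a sterol transporter, -0.24 ± 0.09, Sqle -0.27 ± 0.11 and Hmgcs1 -0.28 ± 0.13. The call was lost without control replicate 3 (median -0.05, adjusted p = 0.693), without 20-fold iodine replicate 2 (adjusted p = 0.078) and without 20-fold iodine replicate 3 (adjusted p = 0.079), and the median was -0.21 without control replicate 2 and -0.07 with the mean of a gene's probes.

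Genes that thyroid hormone induces in brain did not pass as a group, with a median of -0.02 over 20 members, 7 higher and 13 lower (adjusted p = 0.853), and 0.03 without control replicate 2. The thyroid hormone repressed list had a median of -0.08 over 10 members (adjusted p = 0.303), and the list of transporters, deiodinases and receptors 0.00 over 20 members (adjusted p = 0.661). No member of the 3 lists passed adjusted over the list alone or over all genes. Hr, a direct target of the thyroid hormone receptor, differed by 0.10 (95% confidence interval -0.14 to 0.33), and Klf9, another direct target, by -0.03 (-0.27 to 0.22). Dio2, which makes active hormone in astrocytes, differed by 0.06 (-0.40 to 0.52) and Dio3, which inactivates it, by -0.02 (-0.69 to 0.65). The receptor genes Thra and Thrb had 0.02 (-0.23 to 0.26) and -0.11 (-0.35 to 0.14), and Nrgn 0.13 (-0.22 to 0.47). Among the smallest unadjusted p in the induced list were those of Sult1a1 (-0.57 ± 0.27, SE), Pcp2 (-0.34 ± 0.18), Gbp3 (-0.89 ± 0.61), which is also an interferon list gene, and Ppp1r1b (0.16 ± 0.13). The Gbp3 value rests on control replicate 3, with log2 signals of 5.95 and 7.66 in controls and 5.73 and 6.10 in iodine, and was -0.04 without that array. In the repressed list they were those of Cirbp (-0.16 ± 0.07), Mc4r (-0.51 ± 0.26), Agbl3 (-0.14 ± 0.08) and Mamdc2 (-0.60 ± 0.33), and in the third those of Dio1 (-0.23 ± 0.09), Rxra (-0.12 ± 0.09) and Rxrg (0.11 ± 0.08). Dio1 had another kept probe at -0.003 and Rxra another at 0.45.

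Myelin and oligodendrocyte genes had a median of 0.12 over 25 members (adjusted p = 0.081), with Mbp, myelin basic protein, at 0.31 ± 0.08 (SE), Mobp at -0.31 ± 0.07 and Myrf, well above background on 1 of 2 control arrays, at 0.61 ± 0.14. Mobp had another kept probe at -0.09, and the probes of Mbp ranged from -0.13 to 0.31. The oligodendrocyte precursor list had a median of 0.04 over 13 members (adjusted p = 0.161), and in it Enpp6 alone passed adjusted over the list alone, followed by C1ql1 at 0.47 ± 0.12. Astrocyte genes had a median of -0.08 over 20 members (adjusted p = 0.475), with Gfap at 0.29 ± 0.09, Sox9 at 0.37 ± 0.09 and the tissue factor gene F3 at -0.36 ± 0.11. Microglia genes had -0.03 over 22 members (adjusted p = 0.698), with Aif1 at 0.00 ± 0.14, P2ry12 at -0.24 ± 0.10 and Laptm5 at -0.18 ± 0.10. Inflammatory genes had -0.10 over 22 members (adjusted p = 0.161), with the inflammasome gene Nlrp3 at -0.37 ± 0.08 and the chemokine gene Ccl5 at -0.86 ± 0.20. Without control replicate 2 the myelin (0.08, adjusted p = 0.037), precursor (0.17, adjusted p = 0.026), microglia (-0.15, adjusted p = 0.0088) and inflammatory (-0.19, adjusted p = 0.0020) lists passed. The myelin list also passed with quantile normalization (adjusted p = 0.035, or 0.044 after normexp), and the inflammatory list with no filter (-0.19, adjusted p = 0.019) and without 20-fold iodine replicate 3 (-0.20, adjusted p = 0.019). The inflammatory median was 0.01 with normexp (adjusted p = 0.574), -0.04 with normexp and quantile normalization and 0.00 without 20-fold iodine replicate 2, and the microglia median was 0.07 without control replicate 3 and 0.04 without 20-fold iodine replicate 3.

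Neuronal lists did not pass, although 3 of them did in some alternatives. Immediate early genes, which neuronal activity induces, had a median of -0.12 over 25 members (adjusted p = 0.082), with Npas4 at 0.47 ± 0.07 (SE), Ccn1 at -0.45 ± 0.11, Fos at -0.34 ± 0.22 and Arc at -0.18 ± 0.28. Glutamate receptor and postsynaptic genes had 0.03 over 37 members (adjusted p = 0.081), with the kainate receptor gene Grik2 at 0.37 ± 0.07 and the scaffold gene Shank3 at 0.35 ± 0.07. Presynaptic genes had 0.01 over 32 members (adjusted p = 0.174), with the vesicular glutamate transporter gene Slc17a7 at 0.40 ± 0.08 and Unc13a at 0.31 ± 0.11. Interneuron markers had -0.10 over 19 members (adjusted p = 0.187), with Cort at -0.32 ± 0.09, Gad1, which makes GABA, at -0.20 ± 0.08 and Pvalb at -0.14 ± 0.09. GABA receptors had -0.05 over 15 members (adjusted p = 0.487), with Gabrg1 at -0.32 ± 0.10 and Gabra3 at -0.47 ± 0.15. Both had another kept probe near 0, at -0.03 for Gabrg1 and 0.02 for Gabra3. Monoamine, cholinergic and stress peptide receptors had 0.00 over 38 members (adjusted p = 0.398), with Adra1d at 0.39 ± 0.09 and Drd1 at 0.28 ± 0.09. Ion channels had 0.04 over 37 members (adjusted p = 0.184), with Cacna1e at 0.32 ± 0.10 and Hcn2 at 0.45 ± 0.15. Immediate early genes passed with normexp (adjusted p = 0.014, or 0.044 with quantile normalization), no filter (adjusted p = 0.024), the mean of probes (adjusted p = 0.046) and without control replicate 2 (-0.19, adjusted p = 0.0020). Glutamate receptor genes passed with quantile normalization (adjusted p = 0.035, or 0.032 after normexp) and without 20-fold iodine replicate 3 (0.09, adjusted p = 0.0046), and channels with the mean of probes (0.07, adjusted p = 0.0037) and without 20-fold iodine replicate 3 (0.09, adjusted p = 0.0145). Without 20-fold iodine replicate 2 the medians of these 2 lists were 0.00 and -0.01.

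Neurotrophins and their receptors had a median of 0.02 over 20 members (adjusted p = 0.557), with Bdnf at -0.20 ± 0.22 (SE), Nrg3 at -0.14 ± 0.08 and Gfra1 at 0.23 ± 0.12. Neurogenesis genes had 0.03 over 21 members (adjusted p = 0.174), with Dcx, a marker of immature neurons, at -0.05 ± 0.12, Hes5 at 0.33 ± 0.08 and Nes at 0.27 ± 0.07, and passed with the mean of probes (0.10, adjusted p = 0.046) and without control replicate 2 (0.07, adjusted p = 0.021), against a median of -0.05 without control replicate 3. Proliferation genes had -0.01 over 21 members (adjusted p = 0.475), with Ccnb1 and Pcna both at -0.22 ± 0.08. Extracellular matrix and axon guidance genes had 0.02 over 35 members (adjusted p = 0.485), with Acan at 0.33 ± 0.12 and Efna3 at 0.28 ± 0.11. The sex steroid list had a median of 0.00 over 10 members with its camera direction upward (adjusted p = 0.521). In it Esr1, estrogen receptor alpha, passed adjusted over the list alone at -0.41 ± 0.08, with another probe at -0.17. Over all genes limma's adjusted p for Esr1 was 0.668. Greb1, an estrogen-induced gene, had 0.34 ± 0.10.

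Stress and metabolism lists did not pass either, although all 5 passed in some alternatives. Apoptosis genes had a median of -0.09 over 24 members (adjusted p = 0.053), with Bid at -0.22 ± 0.08 (SE). Oxidative stress genes had -0.07 over 30 members (adjusted p = 0.081), with Mt1 at the value above and Mt2 at -0.53 ± 0.16. Unfolded protein and heat shock genes had -0.08 over 24 members (adjusted p = 0.081), with Dnajb9 at -0.34 ± 0.11 and Calr at 0.15 ± 0.07. Respiratory chain genes had -0.04 over 56 members (adjusted p = 0.081), with Ndufa2 at -0.16 ± 0.07 and Cox6c at -0.13 ± 0.07. Ribosomal protein genes had -0.02 over 66 members (adjusted p = 0.456), with Rpl39 at -0.23 ± 0.08 and Rpl37 at 0.36 ± 0.14. The only kept probe of Rpl37 was dim, with log2 signals of 3.87 to 4.45, against a control mean of 12.97 for Rpl39. Apoptosis genes passed in 7 alternatives, with normexp (-0.05), quantile normalization, both together, median scaling, either filter and ranks (adjusted p = 0.0096 to 0.048). With normexp the oxidative stress (adjusted p = 0.0024), unfolded protein (-0.05, adjusted p = 0.042), respiratory chain (-0.06, adjusted p = 2.3e-04) and ribosomal protein (-0.04, adjusted p = 0.0043) lists passed. Oxidative stress, unfolded protein and respiratory chain lists passed with no filter (adjusted p = 0.010, 0.018 and 0.0096), the first and last also with the mean of probes (adjusted p = 0.046 for both), the respiratory chain with median scaling (-0.07, adjusted p = 0.048), and oxidative stress without control replicate 2 (adjusted p = 0.014) and without 20-fold iodine replicate 3 (adjusted p = 0.035).

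Choroid plexus, meninges and ependyma genes varied more between the 2 iodine arrays than between the groups. Choroid plexus genes, with a median of -0.35 over 19 members (adjusted p = 0.462), deviated by -1.19 on iodine replicate 2 and 0.91 on iodine replicate 3, against 0.21 and 0.09 in controls. Ttr, transthyretin, the thyroid hormone carrier made by the choroid plexus, had log2 signals of 14.49 and 14.31 in controls and 12.86 and 15.23 in iodine, and Folr1 and Kcnj13 differed by -0.51 ± 0.64 (SE) and -0.61 ± 0.87. The meninges list had -0.25 over 18 members (adjusted p = 0.240), with Dcn at -0.35 ± 0.22 and Ogn at -0.59 ± 0.38. The medians of both lists turned sign with which iodine array was left out, at 0.71 and 0.26 without 20-fold iodine replicate 2 and -1.38 and -0.81 without 20-fold iodine replicate 3. All 4 passed the threshold, but in opposite directions, depending on which iodine array was kept. Ependyma genes had 0.06 over 13 members (adjusted p = 0.459), with Dnah5 at -0.21 ± 0.08 and Hydin at 0.27 ± 0.19, and turned in the same way, to -0.23 without 20-fold iodine replicate 3 and 0.32 without 20-fold iodine replicate 2, with -0.04 without control replicate 2. Endothelium and pericyte genes had 0.05 over 22 members (adjusted p = 0.140), with Kdr at 0.33 ± 0.09 and Emcn at 0.27 ± 0.09, and passed without 20-fold iodine replicate 2 (0.15, adjusted p = 0.011), against -0.01 without 20-fold iodine replicate 3. Red blood cell genes had 0.15 over 8 members (adjusted p = 0.330), with Hbb-b1 at 0.37 ± 0.30, and passed without control replicate 3 (0.40, adjusted p = 2.5e-05), but the median was -0.15 without control replicate 2 (adjusted p = 0.069).

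Region markers gave no call, although 3 lists passed in some alternatives. The CA1 list had a median of -0.09 over 12 members (adjusted p = 0.832), with Gpr161 at 0.52 ± 0.17 (SE) and Dcn as above, and the CA3 and CA2 list 0.07 over 14 (adjusted p = 0.372), with Nectin3 at 0.41 ± 0.13 and Amigo2 at -0.20 ± 0.07. The dentate granule list had a median of 0.05 over 17 members and a camera direction downward (adjusted p = 0.908), with Pdzd2 at -0.32 ± 0.12 and Maml2 at -0.22 ± 0.09. Ventral hippocampus genes had -0.15 over 14 members (adjusted p = 0.106), with the thyrotropin-releasing hormone receptor gene Trhr at -0.44 ± 0.09 and Nr2f2 at -0.29 ± 0.12. Neocortex genes had -0.12 over 15 members (adjusted p = 0.582), with Ccn2 at -0.80 ± 0.33 and Nxph4 at 0.21 ± 0.12. Thalamus and habenula genes had 0.11 over 18 members (adjusted p = 0.174), with Prkcd at 0.70 ± 0.30 and Nwd2 at -0.22 ± 0.08, and striatum and septum genes 0.15 over 16 members (adjusted p = 0.108), with Drd1 as above and Rarb at -0.21 ± 0.09. The ventral hippocampus list passed with normexp (-0.08, adjusted p = 0.039), no filter (adjusted p = 0.047), the mean of probes (adjusted p = 0.046) and without 20-fold iodine replicate 3 (-0.31, adjusted p = 0.0015). Striatum and septum genes passed with normexp (0.09, adjusted p = 0.039, or 0.045 with quantile normalization), without control replicate 2 (adjusted p = 0.036) and without 20-fold iodine replicate 3 (adjusted p = 0.027), and thalamus and habenula genes without control replicate 2 (0.23, adjusted p = 0.025) and without 20-fold iodine replicate 2 (0.27, adjusted p = 6.9e-04), against -0.04 without 20-fold iodine replicate 3.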

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

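All alternatives were planned before the data were examined. No gene passed the adjusted threshold of 0.05 in any of them. The limit of 0.1 was set only on the fit reported first, where 0 genes passed, while with the intensity trend Rn28s1 and Map3k10 had an adjusted p of 0.0786. Of the 20 genes named first, 18 kept their sign in every setting, as did 118 of the 137 genes named in all. The 20 were chosen for arrays that do not overlap, so leaving out 1 array could not change their sign. Apart from the genes fixed in advance, the 137 were picked by small unadjusted p in these same data, so a kept sign is no separate support. Sizes were less stable. Olfr122 ranged from 0.08 to 0.97, Cyp2g1 from 0.20 to 3.24 and Map3k10 from -1.14 to -0.19, while Rn28s1 stayed between 0.76 and 0.85. These ranges include normexp, whose offset of 50 draws the differences of dim genes toward 0. The 6 shifted lists all passed under every background correction, normalization, filter and probe rule (the variance model does not enter camera and tests no list), with 9 lists passing after quantile normalization, 8 with median scaling, 7 with the stricter filter and 7 by camera on ranks. More lists passed with normexp (14, or 11 with quantile normalization), with no filter (13) and with the mean of a gene's probes (12), and 0 passed with an estimated correlation or by fry, and the causes were not tested. The number of lists was 4 to 15 when 1 array was left out. Over all lists and the other settings, 527 of 645 comparisons kept the direction and the side of the threshold, 44 changed sign without a call, 17 lost the call, 54 gained one and 3 reversed. The estimated correlation, ranks, fry and the replicate block leave a list's median as it was, so no median could change sign there. Only 6 of the 43 lists had a call to lose, so the share kept is no measure of how stable those 6 were. The reversed lists were choroid plexus and meninges without 20-fold iodine replicate 2 and ependyma without 20-fold iodine replicate 3. With 1 array left out, their medians ranged from -1.38 to 0.71, from -0.81 to 0.26 and from -0.23 to 0.32, with both ends set by which iodine array was left out.

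The descriptive count of 174 genes fell to 24 with normexp (4 higher, 20 lower), to 21 with normexp and quantile normalization (4 higher, 17 lower) and to 98 with the stricter filter, and it was 441 with no filter and 595 over every probe. With normexp the background method and the signal column changed together, and the cause of its lower counts was not tested. The filters change how many dim genes are tested. Leaving out 1 array gave 325 to 437, where no overlap with a single array, assumed to vary like the other group, is easier to reach. Median scaling gave 171 genes, 71 higher and 100 lower, and quantile normalization 159, 64 higher and 95 lower, against 85 and 89, but the balance of directions turned more with 1 array left out, from 228 higher and 108 lower without 20-fold iodine replicate 2 to 78 and 359 without 20-fold iodine replicate 3. The intensity trend gave 139 and the mean of probes 162. With the replicate number as a block (replicate block) 0 genes passed, 195 reached the descriptive limit and 6 lists passed, so it changed no call. Arrays with the same number did not deviate together (correlation -0.0245 across genes), so the numbers are not taken as pairs. Slide as a block was not run, because all arrays share 1 slide. Normexp used the median spot signal in place of the planned mean. Signal over background limits 17158 probes that were never well above background.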

Other observations

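Leaving out each array was planned as an alternative, but its use as a test of these patterns was chosen after the result was seen, as were the tests that compared Arntl, set the highest microglia marker against the interferon list or counted other splits. The tests of microglia, of T and NK lymphocytes and of further pituitary markers were written before their values were seen.

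Marker transcripts of structures beside the dorsal hippocampus differed between the 2 iodine arrays. Beyond choroid plexus and meninges, thalamus and habenula genes deviated by -0.11 on iodine replicate 2 and 0.36 on iodine replicate 3, against 0.03 and -0.19 in controls, and ependyma genes by -0.22 and 0.26, against -0.12 and 0.06. Red blood cell genes stood lowest on control replicate 2 (-0.34) and at 0.18, 0.01 and 0.12 on the other arrays. None of these lists passed between the groups.

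Interferon and antigen presentation genes were lower in the iodine group, and the difference rests largely on control replicate 3: without it the interferon median was -0.0696. On that array the 26 interferon genes exceeded the mean of the other arrays by a median of 0.65 and the 15 antigen presentation genes by 1.01. A larger number of microglia as the whole source is argued against, since the highest excess of any of the 22 microglia markers was 0.339. Their median of 0.175 fell between the bounds set beforehand (0.1 and 0.2), so a smaller contribution stays open. The markers were used as a measure of the number of microglia, and a response within microglia was not tested. T and NK lymphocytes cannot be told apart from other sources: the median excess of 13 detected markers was -0.0019, but many lie near the detection floor and Cd3e and Cd4 have a high baseline (control means of 7.07 and 9.12 log2), so the planned bound was wrong for them, and over the 7 markers of usable level (1 to 4 log2 units above the floor, a limit set afterwards) the median was 0.13 with 5 higher. An interferon response in 1 control sample and an effect of iodine both stay open, and slide position is confounded with group.

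Clock genes that peak with Dbp and the Per genes were lower in iodine in 8 of 8 members, by a median of -0.50. But Nr1d1, left out of that set, was higher by 0.47, and with it the count is 8 of 9. The set was not among the lists fixed beforehand and was taken from the list that passed, so its count is no separate support. A single array is argued against, since with each array left out in turn the median of the whole list of 17 came no nearer 0 than -0.184. The whole list also kept its call by camera with the preset correlation. That call adds little, since the same test passed a simulated list shifted on 1 array alone. With all 4 arrays the list did not pass by camera with an estimated correlation (adjusted p = 0.80) or by fry (adjusted p = 0.46). A candidate explanation is a different time of day at tissue collection, which would move Arntl the other way. Arntl differed by 0.302 in that direction, but with 2 arrays per group it did not pass, and the median over 5 clock genes of its phase was 0.09. Time of collection, slide position and iodine intake cannot be told apart here.

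The hormone list was higher in iodine, most in Gh, Prl and Cga (median 1.97), which were picked after their values were seen. A single array is argued against for the list, since with each array left out in turn the median of all 13 members came no nearer 0 than 0.282. The list also kept its call by camera with the preset correlation. That call adds little, since the same test passed a simulated list shifted on 1 array alone. With all 4 arrays the list did not pass by camera with an estimated correlation (adjusted p = 0.80) or by fry (adjusted p = 0.50). Pituitary tissue or RNA carried into the samples may raise all of them together. The median over 7 other pituitary markers was -0.0256, below the bound set beforehand, but that bound was wrong for these markers, since only 3 of them (Lhx3, Gata2 and Nr5a1, median 0.20 with 2 of 3 higher) had a usable level, by the same limit set afterwards, and Chgb and Scg2 are abundant in hippocampus (control means of 13.96 and 11.59 log2), which would hide a small share. Carry-over and a change in hippocampal expression both stay open.

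The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 174 genes past the descriptive limit and the highest other split 205, so 2 of the 3 splits gave at least as many, while genes with an unadjusted p under 0.05 numbered 1239 in the real split against 675 and 821. For gene lists the real split gave 6 and the highest other 14, so 3 of the 3 splits gave at least as many. The interferon and cholesterol lists passed in all 3 splits and antigen presentation in 2 of 3. The glucocorticoid (adjusted p = 1.3e-05, against 0.249 and 0.066), clock (0.0056, against 0.620 and 0.760) and hormone (0.0056, against 0.169 and 0.879) lists passed in the real split alone. These 3 lists are compared because they passed in the real split. Each of the other splits also had lists that passed in it alone, among them inflammatory and endothelium genes in 1 and microglia and proliferation genes in the other. Passing in a single split therefore does not set the real one apart.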
